A study of Macaca mulatta with 5 samples.

How the data were processed

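The libraries were 5, namely NESC at passages 5, 24 and 36, RGPC and neurons. Per the submitters, mRNA was fragmented, copied with random primers, made into TruSeq libraries and sequenced on an Illumina HiSeq, and reads were aligned by the authors with TopHat2 2.0.9. The program that counted reads, the genome build and the annotation are not given in the sources used here. The deposited table holds 16970 Ensembl genes of Macaca mulatta. Per the file headers it gives FPKM, a fragment count scaled by transcript length and library size, although the table's title speaks of RPKM, and the plan, which assumed RPKM, was applied to FPKM. It also gives a normalized count per library, a deposited signal that the values show to be whole reads multiplied by 1 factor per library. Dividing by that factor gave whole reads, within 0.1 read, for all values of 4 libraries and all but 1 value of the passage 36 NESC library. The recovered reads ranged from 5403437 to 7899991 per library. No confidence intervals were computed for single values, and reads per gene are given where they are few.

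Gene symbols came from the deposited table for 10977 genes. Annotation tables of a later assembly, used for names only, gave 2204 more through the RefSeq peptide and 1291 through the gene ID, and 2498 genes had no symbol. A locus was shared by 2397 genes with at least 1 other gene. Of all values 11.9% were 0, and some zeros stood beside high values: 32 genes had at least 300 reads in 1 library and 0 in another. Examples are YBX1, SLC38A1 (0 reads in NESC P36, at least 1368 in the other libraries) and ASCC3 (0 reads in NESC P36, at least 488 elsewhere), so a gene listed at 0 is called that and is given no fold change. The ratio of FPKM to reads, which should be the same for a gene in every library after scaling, differed more than 2-fold between libraries for 94 of 9551 genes with at least 20 reads in all (0.984%).

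These choices were made before the data were examined: the groups, the tests, the filter, the gene lists, the rule for named genes and most alternatives. Genes were tested with limma 3.58.1 in R 4.3.3, in its trend form, on log2(FPKM + 1), for the 14571 genes with FPKM of at least 1 in at least 1 library. The tests were two-sided, with a Benjamini-Hochberg adjusted p threshold of 0.05 over all genes of a comparison. RGPC against NESC, neurons against NESC and neurons against RGPC came from a model with 3 groups, which leaves 2 residual degrees of freedom, all from the NESC passages. Passage 5 against passages 24 and 36 came from a model with 4 groups and 1 residual degree of freedom. The lone libraries were assumed to vary like NESC. Values after ± are standard errors of the log2 fold change from limma. Every adjusted p in the text is from limma, or from camera in limma for gene lists, unless edgeR is named.

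There were 32 gene lists of 512 entries, of which 427 were in the table, and 30 lists could be tested in each comparison. They were tested with camera with a preset correlation of 0.01, and beside it with camera with an estimated correlation and with fry, adjusted over the lists of a comparison. With an estimated correlation camera rests on the few residual degrees of freedom, and no list passed in any comparison. For WNT targets in RGPC the estimate, −0.069, lay below the preset, yet the unadjusted camera p rose from 0.00484 to 0.0965. A call lost there need not come from correlated members. Counts of members that rose or fell use the adjustment over all genes, and counts adjusted over the list alone are given beside them.

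The rule for named genes took, for each comparison of cell types, the 8 highest and 8 lowest log2 fold changes among genes past the threshold with a symbol and FPKM of at least 5 in a compared group. Where fewer than 8 passed, genes at least 2-fold apart and outside the NESC range filled the places and are said not to have passed. The rule also took up to 4 members of each described list by absolute log2 fold change, and a set of 15 marker genes. For the passages it took 5 genes in each direction. Because many genes so chosen had few reads, the same rule with at least 50 reads in a compared library was added. A few other list members were chosen after their values were seen, as were POU5F1, HOXC8, and genes of pathways named to describe a list.

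Some alternatives were chosen after seeing the data: the edgeR 4.0.16 quasi-likelihood test on recovered reads, the requirement of at least 20 reads in at least 1 library, and the named-gene rule with 50 reads. Settings tried as fixed in advance were other pseudocounts, no filter, a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, variance moderation without a trend or in robust form, a model with only the compared groups, and leaving out each NESC library. The tests were tried on simulated data with 200 changed genes. In these, limma on all genes recovered 0% of changes of log2 3 for RGPC and for neurons, limma on genes with at least 20 reads recovered 90% and 92%, and edgeR recovered 96% and 98%. The changed genes were all well read in NESC. On the deposited data limma on all genes called 4013 genes in neurons, so the 0% does not describe that test. Simulated genes of like read level had the same spread, so the higher shares do not give the power on the deposited data either. Unchanged lone libraries were simulated 20 times, and limma then called a mean of 12.2 genes (range 6 to 20) for RGPC, all with fewer than 20 reads. The simulated counts were drawn around NESC means, so a gene without reads in NESC could gain none. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. No sample or value column was left out.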

Results

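RNA sequencing measured gene expression in 5 libraries of rhesus macaque neural cells grown from embryonic stem cells. Neuroepithelial stem cells (NESC), the earliest progenitors of the neural tube, were sequenced at passages 5, 24 and 36, with 1 library each. They were kept in medium with 3 µM CHIR99021 (a GSK3 inhibitor that activates WNT signalling), 5 µM SB431542 (a TGF-beta receptor inhibitor), 10 ng/ml bFGF and 1000 U/ml human LIF. Radial glial progenitor cells (RGPC) were made from passage 36 by 7 days in the same medium without CHIR99021. Neurons were made from passage 36 by 13 days in differentiation medium on laminin and gelatin, and RGPC and neurons had 1 library each. The submitters scored passaging as single cells with self-organisation into neural tubes as moderate at passage 5, strong at passages 24 and 36, weak in RGPC and absent in neurons.

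Wherever 3 NESC values are listed, they stand in the order of passages 5, 24 and 36. The reads recovered per library came to 6808232, 5620416 and 7899991 in NESC, 6165818 in RGPC and 5403437 in neurons. Of 16970 genes in the table, 15022, 14754 and 14663 were above 0 in NESC, 15072 in RGPC and 15272 in neurons. The 10 genes with the most reads held between 4.46% and 5.71% of the reads of a library. RGPC and neurons had no replicates, so each gene's p-value in their comparisons measures only the spread between the 3 NESC passages. The sources used here do not say whether the libraries were separate cultures. For passage 5 against later passages the spread is that between passages 24 and 36. List p-values from camera with the preset correlation set members against other genes as nearly independent values and measure no spread between cultures. In the model with 3 groups the estimated correlation was 0.43 for cell cycle and 0.70 for glycolysis. Gene positions are as deposited, and the genome build is not given in the sources used here.

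The NESC libraries were compared with each other to see how far the cells stayed alike over many passages. All 3 carried high levels of neural progenitor transcripts. SOX2, a transcription factor of neural stem cells, stood at 153, 201 and 201 FPKM, and NES, which encodes the progenitor filament nestin, at 348, 467 and 470 FPKM. PAX6, a neural patterning factor, was at 98.8, 82.2 and 42.4 FPKM, and LIN28A, an RNA-binding protein of early progenitors, was at 178, 327 and 309 FPKM. The pluripotency factor POU5F1 was at 0.304, 0.172 and 0.251 FPKM, and SOX1 was not in the table. FABP7, a fatty acid carrier of radial glia, varied widely, from 1505 FPKM at passage 5 to 980 at passage 24 and 193 at passage 36.

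Across the 14571 genes tested, Pearson's r of log2(FPKM + 1) was 0.92 between passages 5 and 24, 0.92 between passages 5 and 36 and 0.93 between passages 24 and 36. Genes are not independent replicates, so these values describe likeness and test nothing. Genes at least 2-fold apart numbered 1669, 1793 and 1155 in the same pairs. Among genes with at least 20 reads in a library they numbered 991, 1115 and 559. Passage 36 NESC and RGPC gave r = 0.90, with 1939 genes at least 2-fold apart, or 1267 with at least 20 reads (866 higher and 401 lower in RGPC). Passage 36 NESC and neurons gave r = 0.74 and 6175 such genes, and RGPC and neurons gave r = 0.75 and 5102.

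RGPC were compared with NESC to see what followed the withdrawal of CHIR99021. No gene discussed in this paragraph passed the limma test. Targets of WNT and beta-catenin were mostly lower in RGPC. LEF1 (ENSMMUG00000023256, chromosome 5, 100975189 to 101096845), a partner of beta-catenin and itself a WNT target, stood at 13.0, 20.4 and 21.3 FPKM in NESC and at 0.144 FPKM, or 2 reads, in RGPC (log2 fold change −4.04 ± 0.39 SE, adjusted p = 0.143). NKD1, a feedback inhibitor of WNT signalling, was at 13.2, 5.71 and 13.9 FPKM against 0.717 in RGPC (−2.71 ± 0.62). APCDD1, another WNT inhibitor, was at 64.8, 107 and 90.9 FPKM against 30.5 (−1.46 ± 0.35), and AXIN2, a scaffold of the beta-catenin destruction complex, at 38.9, 27.8 and 85.1 FPKM against 19.3 (−1.19 ± 0.76). The transcription factor SP8 went the other way, at 17.2, 17.4 and 14.4 FPKM against 59.1 (1.80 ± 0.18, adjusted p = 0.157).

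As a list, WNT targets fell in RGPC (camera, adjusted p = 0.0363), with 11 of 13 members lower. The call was lost without NESC P5 (adjusted p = 0.0509) and with an estimated correlation (adjusted p = 0.785), where no list passed in any comparison. None of these 13 passed over all genes, and adjusted over the list alone 1 rose (SP8) and 1 fell (LEF1). Targets of FGF and ERK also fell as a list (adjusted p = 0.0363, and adjusted p = 0.785 with an estimated correlation), with 12 of 14 members lower and 0 past the limma test. That call was lost without NESC P24 (adjusted p = 0.139) and without NESC P36 (adjusted p = 0.0690). EGR1 (ENSMMUG00000018025, chromosome 6, 134881997 to 134885796), an immediate early gene induced by ERK, was at 35.2, 215 and 253 FPKM against 3.35 in RGPC (−4.85 ± 1.45, adjusted p = 0.338). FOS, another immediate early gene, was at 6.22, 11.4 and 24.0 FPKM against 1.36 (−2.47 ± 0.85). DUSP6, a phosphatase that switches ERK off, was at 29.6, 119 and 97.1 FPKM against 23.9, while DUSP5, another, lay within the NESC range at 5.67 FPKM.

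Glycolysis fell as a list in RGPC (camera, adjusted p = 0.000115, and adjusted p = 0.785 with an estimated correlation), with 19 of 20 members lower and 0 past the limma test. LDHA, which makes lactate, was at 784, 249 and 523 FPKM against 123 (−1.91 ± 0.78). HK2, which phosphorylates glucose, was at 87.5, 22.5 and 22.5 FPKM against 10.3, and BNIP3, induced by hypoxia, at 529, 43.8 and 116 FPKM against 40.8. The list for the unfolded protein response, which includes amino acid response genes, fell too (adjusted p = 0.0173, and adjusted p = 0.785 with an estimated correlation), with 13 of 15 members lower. ASNS, which makes asparagine, was at 250, 115 and 325 FPKM against 27.2 (−2.91 ± 0.72, adjusted p = 0.315), and PHGDH, the entry enzyme of serine synthesis, at 238, 179 and 312 FPKM against 90.5. The stress factors DDIT3 (8.39, 11.9 and 64.7 FPKM against 6.85) and TRIB3 (0.577, 2.19 and 17.8 FPKM against 0.871) were high mainly in NESC P36, and without that library the list gave adjusted p = 0.0769. By fry the 4 list calls in RGPC (WNT targets, FGF and ERK targets, glycolysis and unfolded protein response) were lost, with adjusted p = 0.510 to 0.796.

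Radial glial and Notch-related transcripts were mostly higher in RGPC, but neither a gene nor the list passed its test. SOX9 (ENSMMUG00000002412, chromosome 16, 67357425 to 67362825), a transcription factor of gliogenic progenitors, was at 4.85, 4.82 and 2.19 FPKM in NESC and 41.2 FPKM in RGPC (3.15 ± 0.49, adjusted p = 0.270). HES5, a Notch target that holds cells in the progenitor state, was at 22.8, 65.4 and 13.5 FPKM against 122 (2.12 ± 1.04), and NOTCH1 at 20.4, 17.4 and 11.4 FPKM against 38.8 (1.23 ± 0.40). The glutamate transporter SLC1A3 was at 16.8, 37.9 and 23.6 FPKM against 56.6 (1.16 ± 0.53), and TTYH1, a membrane protein of radial glia, at 164, 223 and 81.3 FPKM against 409. FABP7, at 1199 FPKM in RGPC, lay within the NESC range (0.86 ± 1.45, and −0.019 without NESC P36). GFAP, the astrocyte filament, was listed at 0 in all NESC and had 2 reads in RGPC. The radial glia list gave adjusted p = 0.130, with 15 of 23 members higher (adjusted p = 0.785 with an estimated correlation).

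Neuroepithelial transcripts persisted in RGPC at levels close to or above those of NESC. NES was at 518 FPKM (0.29 ± 0.25), SOX2 at 183 FPKM (0.00 ± 0.23) and PAX6 at 136 FPKM (0.94 ± 0.59). DACH1, a nuclear factor of neural rosettes, was at 11.9, 9.18 and 15.7 FPKM against 52.2 (2.03 ± 0.35), CRB2, an apical polarity protein, at 39.6, 32.3 and 39.4 FPKM against 110 (1.55 ± 0.18, adjusted p = 0.196), and ZBTB16, a rosette factor, at 14.3, 37.8 and 24.1 FPKM against 43.9. LIN28A was lower, at 109 FPKM (−1.26 ± 0.45). The list gave adjusted p = 0.177, with 11 of 14 members higher, 0 past the limma test and 1 (CRB2) adjusted over the list alone.

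Proneural and neuronal list members were mostly higher in RGPC, but neither a gene nor a list passed its test on the deposited values. NHLH1, a factor of cells leaving the cycle to become neurons, was at 9.51, 5.06 and 2.50 FPKM against 35.8 (2.60 ± 0.75), and the proneural factor NEUROG1 at 4.68, 3.59 and 0.440 FPKM against 18.0. DCX, a microtubule protein of young neurons, was at 19.2, 10.9 and 5.93 FPKM against 50.7 (2.13 ± 0.72), and TUBB3, the neuronal tubulin, at 265, 302 and 249 FPKM against 547 (1.01 ± 0.16, adjusted p = 0.270). MAP2, a dendrite protein, was at 22.7, 28.0 and 53.5 FPKM against 92.2 (1.48 ± 0.59). STMN2 and L1CAM, proteins of growing axons, were at 110 and 18.0 FPKM, above passages 24 and 36, while passage 5 NESC had 159 and 8.32 FPKM. NEFL was lower, at 101, 301 and 253 FPKM against 81.2. The proneural list (12 of 12 members higher) and the neuronal list (14 of 19) each gave adjusted p = 0.0990 as deposited, with 0 members past the limma test. Without NESC P5 they gave adjusted p = 0.000805 and 0.0497, with at least 20 reads 0.00974 and 0.00755, and by fry 0.761 and 0.510. After quantile normalization both passed with adjusted p = 0.0236, as did the neuroepithelial list, and the radial glia list gave adjusted p = 0.0357. On the deposited values, each of these 4 lists gave adjusted p = 0.785 with an estimated correlation.

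Proliferation genes stayed near NESC levels. MKI67, a marker of cycling cells, was at 70.1, 45.2 and 84.6 FPKM against 69.4 in RGPC (0.10 ± 0.43), with a negative fold change without NESC P24 (−0.15) and by edgeR (−0.055). MCM5, a subunit of the replication helicase, was at 50.7, 58.3 and 82.7 FPKM against 117. The cell cycle list gave adjusted p = 0.797, with 11 members higher and 15 lower, a median log2 fold change of −0.04, a mean of 0.05 and a camera direction of down, which turned after quantile normalization (adjusted p = 0.519), by fry (0.988) and without NESC P36 (0.443).

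Among genes with at least 50 reads in a compared library, none of the genes described here passed the test. SFRP2, a secreted WNT modulator, was at 627, 102 and 59.7 FPKM against 2191 (3.80 ± 1.64). DBX2, a factor of the middle of the dorsoventral axis, was at 4.04, 2.25 and 0.425 FPKM against 43.2 (3.95 ± 0.87), and SHISA3, an inhibitor of WNT and FGF receptors, at 6.28, 1.49 and 2.96 FPKM against 68.1 (4.06 ± 0.74). NEUROG3, a proneural factor, was at 1.5, 1.27 and 0.700 FPKM against 19.9 (3.29 ± 0.31, adjusted p = 0.140), and ROBO3, an axon guidance receptor, at 1.62, 0.563 and 1.61 FPKM against 20.9 (3.31 ± 0.44). MOXD1 and the secretin receptor SCTR were at 44.9 and 8.54 FPKM in RGPC. The largest negative differences included the angiotensin receptor AGTR1, at 57.9, 24.6 and 28.7 FPKM against 0.0809 (−5.04 ± 0.62, adjusted p = 0.205), and CRABP2, which carries retinoic acid, at 413, 809 and 853 FPKM against 77.6 (−3.07 ± 0.55, adjusted p = 0.284). VGF, a secreted neuropeptide precursor, was at 58.4, 205 and 124 FPKM against 10.9, the vascular ligand ANGPT1 at 5.12, 31.1 and 12.1 FPKM against 0.454, and TNFRSF12A at 25.7, 164 and 143 FPKM against 9.17. CSTA, a protease inhibitor, was at 18.8, 41.8 and 38.2 FPKM in NESC and was listed at 0 in RGPC.

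By limma, 104 genes rose and 2 fell in RGPC, and all 106 had fewer than 20 reads in every library, 78 of them 1 read at most. Those with the highest values that carry a symbol were FLJ12892 (1 read given as 602 FPKM), ZNF534, MNP2, CCL4, GNG8, HCRT (10 reads), METTL21EP and CALR3, each listed at 0 in all NESC. MRPL45 and TIMM8B, with at most 6 reads in any library, were listed at 0 in RGPC and did not pass. With at least 20 reads in a library, 0 of 12178 genes passed by limma (1709 at an unadjusted p under 0.05, lowest adjusted p = 0.292). By edgeR, 0 of 13063 passed (1661 at an unadjusted p under 0.05, lowest adjusted p = 0.205), and by limma on all 14571 genes 2050 had an unadjusted p under 0.05. The 106 calls became 0 without NESC P5, without P24 or without P36. Outside the NESC range and at least 2-fold apart were 726 higher and 280 lower of 11722 genes with at least 20 reads. In 20 simulations of an unchanged RGPC library the mean total was 505 (range 467 to 556) of on average 11528 such genes. Simulated genes of like read level had the same spread, so this total is no bar for the observed count. NESC P5 against the later NESC passages gave 482 higher and 361 lower of 11532 such genes, outside a range set by fewer libraries. These counts therefore do not show that RGPC differed from NESC by more than NESC libraries differ from each other. The median log2 fold change of all genes was 0.10, and quantile normalization moved it by −0.13. Small positive values may carry this shift, but not every gene does. MKI67 stayed at 0.10, and FABP7 went from 0.86 to 0.94.

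**Figure D1:**
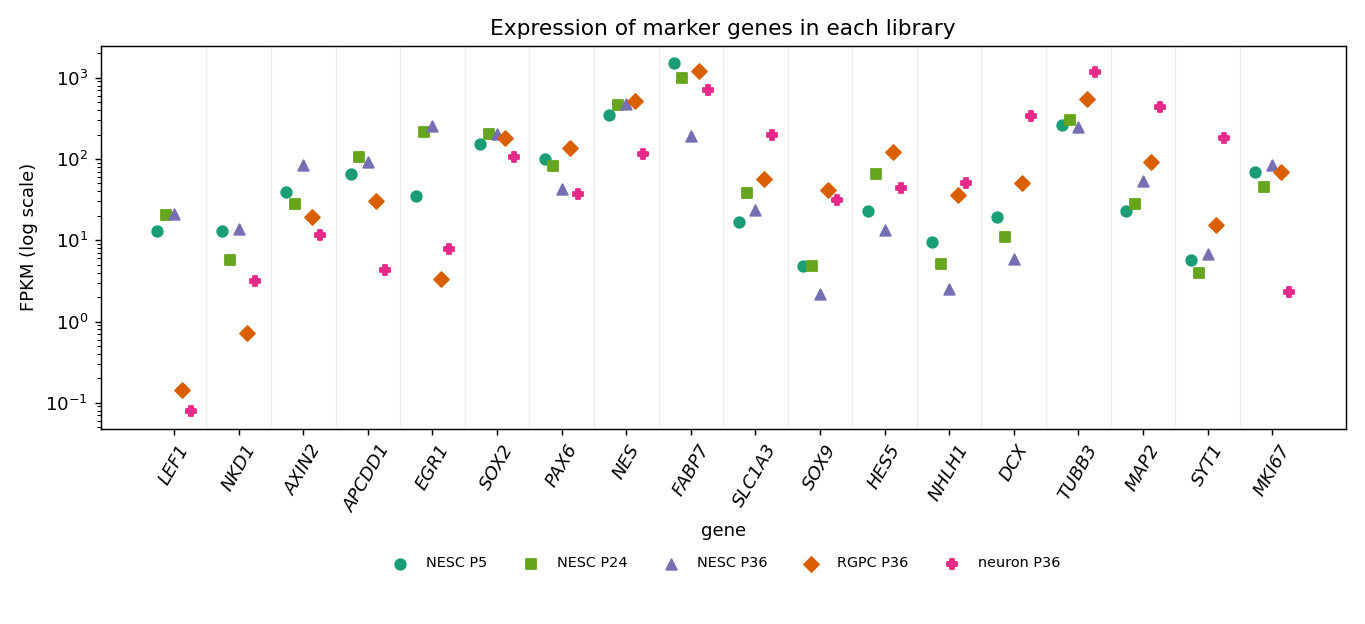
FPKM on a log scale of 18 marker genes (x axis), with 1 point for each of the 5 libraries and no error bars. LEF1 stood at 13.0 to 21.3 FPKM in NESC and at 0.144 in RGPC, and MKI67 at 2.31 in neurons.

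Neurons were compared with NESC to describe what differentiation changed. MAB21L2 (ENSMMUG00000002220, chromosome 5, 142496720 to 143269472), a developmental regulator of eye and midbrain, rose from 0.231, 0.180 and 0.0650 FPKM to 563 (8.93 ± 0.19, adjusted p = 0.00515). Genes of the cell cycle fell and genes of neuronal structure and synapses rose. MKI67 fell to 2.31 FPKM (−4.31 ± 0.43, adjusted p = 0.0208), DCX rose to 338 FPKM (4.84 ± 0.72, adjusted p = 0.0328) and MAP2 to 436 FPKM (3.71 ± 0.59, adjusted p = 0.0358). SYT4, a vesicle protein, rose from 3.83, 0.0416 and 0.119 to 204 FPKM (6.85 ± 1.17, adjusted p = 0.0399).

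In the cell cycle list, 25 of 26 members fell, and 26 adjusted over the list alone (camera, adjusted p = 6.16e-12, and adjusted p = 0.845 with an estimated correlation). RRM2, which makes deoxynucleotides, fell from 135, 191 and 198 to 2.17 FPKM (−5.77 ± 0.29, adjusted p = 0.0112). CCNB2, a mitotic cyclin, fell from 92.1, 70.0 and 90.1 to 1.66 FPKM (−4.99 ± 0.22, adjusted p = 0.00974). TYMS, of thymidylate synthesis, fell from 355, 382 and 387 to 14.7 FPKM (−4.58 ± 0.10, adjusted p = 0.00531), and the mitotic cyclin CCNB1 from 278, 183 and 318 to 9.08 FPKM (−4.65 ± 0.39). SPC24, of the kinetochore, fell from 20.3, 25.9 and 41.9 FPKM and was listed at 0 in neurons (adjusted p = 0.0211).

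The neuronal list rose (camera, adjusted p = 3.34e-05, and adjusted p = 0.845 with an estimated correlation), with 13 of 19 members past the limma test and 14 adjusted over the list alone. MAPT, which encodes tau, rose from 2.86, 1.74 and 2.03 to 119 FPKM (5.23 ± 0.30, adjusted p = 0.0118), and TUBB3 to 1179 FPKM (2.12 ± 0.16, adjusted p = 0.0158). MYT1L, a neuronal identity factor, rose from 0.597, 0.309 and 0 to 50.6 FPKM. STMN2, at 1916 FPKM, did not pass (6.06 ± 2.11, adjusted p = 0.126), and its NESC values ranged from 6.10 to 159 FPKM. Of the synaptic list, 13 of 21 members rose, and 18 adjusted over the list alone (camera, adjusted p = 2.82e-06, and adjusted p = 0.845 with an estimated correlation). RAB3A, a vesicle GTPase, rose from 6.34, 2.44 and 2.58 to 215 FPKM (5.59 ± 0.59, adjusted p = 0.0223). SYP, a vesicle membrane protein, rose from 3.41, 0.535 and 1.17 to 100 FPKM (5.37 ± 0.74), and GRIA2, an AMPA receptor subunit, from 7.42, 1.65 and 3.33 to 183 FPKM (5.32 ± 0.79).

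Of the neurotransmitter list, 19 members were in the table and 8 reached FPKM of 1 in a library and were tested. Of these 8, 5 rose, and 6 adjusted over the list alone (camera, adjusted p = 0.00530, and adjusted p = 0.845 with an estimated correlation). SLC32A1, GAD2 and NR4A2 were under 1 FPKM in all NESC and were tested only because a library outside NESC was higher. The filter thus favours a rise, and neither the count nor the list p-value is free of it. SLC32A1 (ENSMMUG00000003376, chromosome 10, 25723846 to 25728737), which loads GABA and glycine into vesicles, rose from 0.127, 0.135 and 0 to 29.3 FPKM, or 198 reads (adjusted p = 0.00647). GAD2, which makes GABA, rose from 0.784, 0.0898 and 0 to 17.5 FPKM (adjusted p = 0.0232), and NR4A2, a factor of dopaminergic and other neurons, from 0.201, 0.302 and 0.434 to 14.1 FPKM (3.52 ± 0.16). GAD1, the other GABA enzyme, was at 12.2 FPKM and did not pass (2.84 ± 0.75, adjusted p = 0.0788). The vesicular glutamate transporter SLC17A6, chosen after its values were seen, was at 0.813 FPKM in neurons and listed at 0 in the other libraries.

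Neuroepithelial transcripts fell as a list (camera, adjusted p = 0.0123, and adjusted p = 0.845 with an estimated correlation). Of 14 members, 5 fell and 1 rose, and adjusted over the list alone 6 fell and 1 rose. LIN28A fell to 6.16 FPKM (−5.20 ± 0.45, adjusted p = 0.0183), PROM1, an apical membrane protein, from 28.7, 25.0 and 32.6 to 1.74 FPKM (−3.43 ± 0.22, adjusted p = 0.0130) and NES to 114 FPKM (−1.89 ± 0.25, adjusted p = 0.0276). DACH1 rose to 59.8 FPKM. SOX2 (105 FPKM, adjusted p = 0.0880), PAX6 (37.0 FPKM, adjusted p = 0.321), SOX3 (41.0 FPKM) and the growth regulator HMGA2 (87.0 FPKM, adjusted p = 0.0505) were lower without passing, as was ZBTB16 at 9.61 FPKM.

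Radial glial members moved both ways. Of 23 members, 6 rose and 1 fell, and adjusted over the list alone 6 rose and 2 fell, so the list gave adjusted p = 0.294. SLC1A3 rose to 200 FPKM (2.97 ± 0.53, adjusted p = 0.0433) and SOX9 to 31.2 FPKM (2.76 ± 0.49, adjusted p = 0.0431). The gliogenic factor NFIA rose from 0.614, 0 and 0 to 5.09 FPKM, and GFAP, at 1.78 FPKM, had 5 reads. FABP7 was at 704 FPKM (0.10 ± 1.45, with a negative fold change of −0.79 without NESC P36 and −0.36 by edgeR) and HES5 at 44.6 FPKM, and neither passed.

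WNT targets fell as a list (camera, adjusted p = 0.0411, adjusted p = 0.845 with an estimated correlation, and adjusted p = 0.0698 without NESC P5), with 3 of 13 members past the limma test and 5 adjusted over the list alone. LEF1 fell to 0.0788 FPKM, or 1 read (−4.13 ± 0.39, adjusted p = 0.0196), and APCDD1 to 4.34 FPKM (−4.02 ± 0.35, adjusted p = 0.0183). AXIN2, at 11.8 FPKM (−1.86 ± 0.76, adjusted p = 0.164), and the receptor LGR5, at 1.78 FPKM, did not pass. Targets of FGF and ERK gave the same camera value (adjusted p = 0.0411, adjusted p = 0.845 with an estimated correlation, adjusted p = 0.102 without NESC P24 and 0.201 by fry), with 2 of 14 members fallen over all genes and over the list alone. CCND2, a G1 cyclin, fell from 18.4, 31.7 and 31.6 to 2.69 FPKM (−2.90 ± 0.42, adjusted p = 0.0319).

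Glycolysis fell as a list (camera, adjusted p = 0.0123, adjusted p = 0.845 with an estimated correlation, and adjusted p = 0.126 by fry, where the call was lost), with 4 of 20 members past the limma test and 2 adjusted over the list alone. SLC2A1, the main glucose importer, fell from 694, 698 and 629 to 24.3 FPKM (−4.74 ± 0.12, adjusted p = 0.00591), while the neuronal enolase ENO2 was at 35.5, 3.86 and 8.00 FPKM against 94.9 without passing. Cholesterol synthesis fell as a list (adjusted p = 0.0471, and adjusted p = 0.845 with an estimated correlation), with 3 of 16 members past the limma test and 2 adjusted over the list alone. That call was lost after quantile normalization (adjusted p = 0.207), with a pseudocount of 0.1 (0.0595), with at least 20 reads (0.0667), by fry (0.197) and without NESC P24 (0.180). FDPS, an enzyme of the isoprenoid branch, fell from 502, 568 and 526 to 178 FPKM (−1.57 ± 0.13). Of the hindbrain and HOX list, 3 of 14 members rose over all genes and over the list alone, and the list gave adjusted p = 0.655, with a median and a mean below 0 and a camera direction of up. HOXC4, a cervical and hindbrain patterning factor, rose from 11.8, 16.8 and 14.9 to 95.2 FPKM (2.65 ± 0.26, adjusted p = 0.0203), and HOXA2, of the hindbrain, from 16.2, 21.6 and 13.1 to 79.4 FPKM (2.19 ± 0.34, adjusted p = 0.0342).

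Other large changes included the RNA-binding proteins CELF5 (1.04, 0 and 0 to 109 FPKM) and CELF4 (0.812, 0 and 0 to 84.7 FPKM), and HMP19, a neuronal vesicle protein (1.54, 0 and 0 to 313 FPKM). C1ORF61, ERFL and BCL11A, the last a cortical and spinal neuron factor, were listed at 0 in all NESC and had 390, 50 and 385 reads in neurons. ANXA2, a membrane-binding protein, fell from 90.8, 201 and 179 to 1.17 FPKM (−6.11 ± 0.58, adjusted p = 0.0198), and the apoptosis gene PMAIP1 fell as well (−4.98 ± 0.34, adjusted p = 0.0142). LEMD1, HIST2H2BF, APOC1, SMCO4 and TMEM167A passed on at most 5 reads per library. MTO1 fell in FPKM (−6.03 ± 0.96) but not in reads (edgeR, −0.91, not past the threshold).

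By limma, 2081 genes rose and 1932 fell in neurons, and 469 of these 4013 had fewer than 20 reads in every library. Without NESC P5 the total was 927, and without P24 or without P36 it was 0 (5157 and 5357 at an unadjusted p under 0.05). edgeR gave 2471 up and 2309 down, and 3313 genes were called by both tools.

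**Figure D2:**
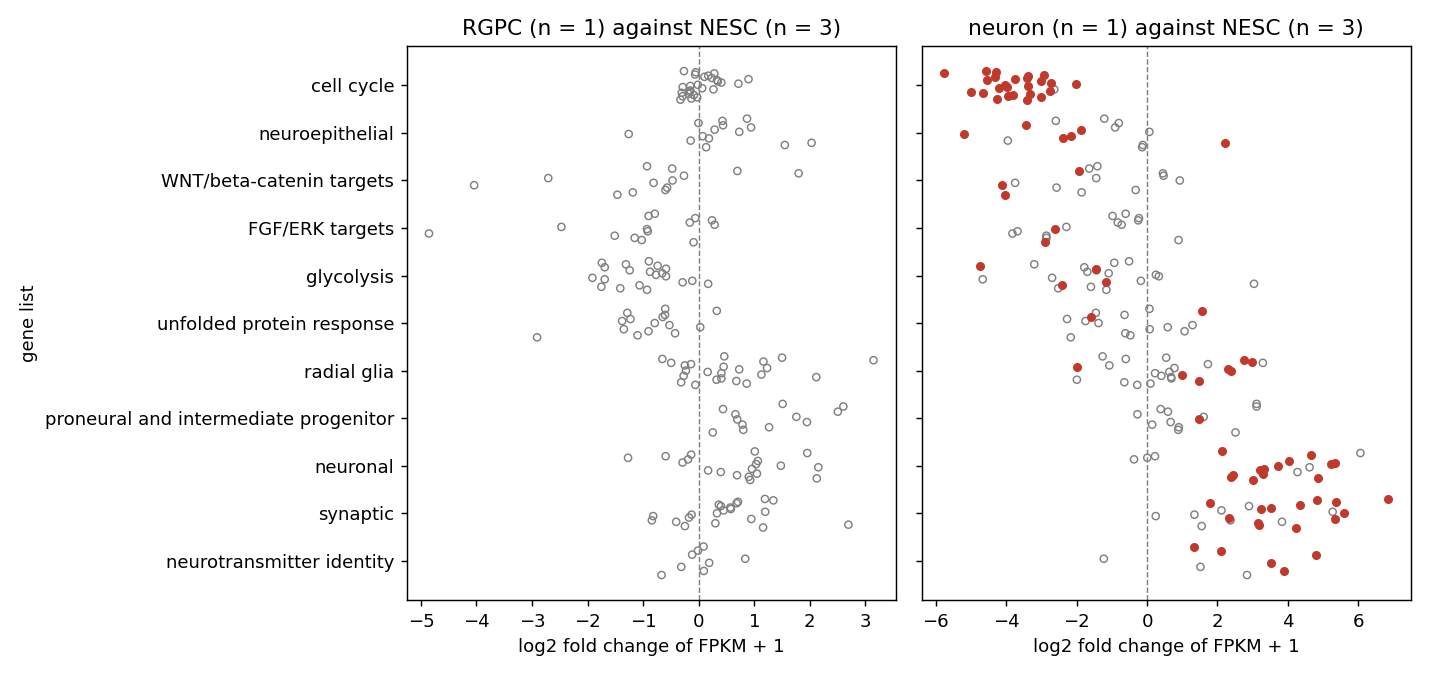
Log2 fold change of FPKM + 1 (x axis) for the members of gene lists in RGPC and in neurons against NESC, with 1 point per gene, red where the limma test passed and open grey where not, and genes listed at 0 in a group at their fitted value. In neurons 25 of 26 cell cycle members fell, and in RGPC 0 did.

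Neurons were also compared with RGPC, 1 library against 1, to see which differences separate neurons from RGPC. MAB21L2 rose from 1.30 to 563 FPKM (7.94 ± 0.24). RRM2 fell from 209 to 2.17 FPKM (−6.05 ± 0.36), CDT1, which licenses replication origins, from 96.9 to 1.56 FPKM (−5.26 ± 0.38) and MCM3, of the replication helicase, from 105 to 2.62 FPKM (−4.88 ± 0.34). MKI67 fell by 4.41 on the log2 scale (SE 0.53, adjusted p = 0.0461). Neuronal factors rose, with ACTL6B, a chromatin remodelling subunit of neurons, going from 0.633 to 103 FPKM (5.99 ± 0.68), MYT1L from 0.0449 to 50.6 FPKM (5.63 ± 0.41) and MAPT from 5.50 to 119 FPKM (4.20 ± 0.36).

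The cell cycle list fell between RGPC and neurons (camera, adjusted p = 1.00e-12), with 15 of 26 members past the limma test and 26 adjusted over the list alone. Synaptic (adjusted p = 2.38e-07) and neuronal (adjusted p = 4.00e-06) lists rose, with 3 of 21 and 4 of 19 members past the limma test, and 13 and 11 adjusted over the list alone. The neurotransmitter list rose (adjusted p = 0.000494, with 4 of 8 members past the test and 6 adjusted over the list alone), and SLC32A1, listed at 0 in RGPC, and NR4A2 were among the 4. The FPKM filter favours a rise of this list here too. The neuroepithelial list fell (adjusted p = 0.000311, with 2 of 14 members past the test and 6 adjusted over the list alone), with PROM1 going from 39.1 to 1.74 FPKM (−3.87 ± 0.26, adjusted p = 0.0210) and NES at 518 against 114 FPKM just short of the threshold (−2.18 ± 0.30, adjusted p = 0.0535). Each of these 5 lists gave adjusted p = 0.899 with an estimated correlation. By fry the neurotransmitter list passed (adjusted p = 0.0261), and the cell cycle (0.0637), synaptic (0.0952), neuronal (0.0637) and neuroepithelial (0.0663) calls were lost. LEF1 was near its floor in both cell types (−0.08 ± 0.47, adjusted p = 0.931). DCX (2.71 ± 0.88, adjusted p = 0.159) and TUBB3 (1.11 ± 0.20, adjusted p = 0.0720) were higher in neurons without passing.

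ANXA2, LITAF (158 to 3.34 FPKM), a regulator of endosomes, and RMI2 (86.3 to 1.65 FPKM), of DNA repair, fell too. HMP19, C1ORF61, BCL11A and ERFL rose from RGPC values listed at 0. FLJ12892, TMEM167A, CCL4, MNP2, MRPL45 and HIST2H2BF passed on at most 5 reads per library. By limma, 565 genes rose and 536 fell, of which 338 had fewer than 20 reads in every library. With at least 20 reads, 753 rose and 1083 fell, and edgeR gave 722 and 877, with 614 genes called by both tools. Without NESC P5 the total of 1101 became 530, and without P24 or without P36 it became 0 (3660 and 3798 at an unadjusted p under 0.05).

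The changes from NESC that RGPC and neurons shared were counted next. LEF1 was near 0 in both, at 2 reads in RGPC and 1 in neurons against 203, 264 and 386 in NESC, and it passed the test in neurons and not in RGPC. SOX9, SLC1A3, DCX and MAP2 were higher in both, and CRABP2 and EGR1 lower. By limma, 20 genes rose and 1 fell in both comparisons, where independent lists would share 14.9 and 0.265. In 20 simulations of unchanged lone libraries against the same NESC, the shared total averaged 4.75 (range 1 to 10), from lists averaging 12.2 and 13.25 calls. These lists were far shorter than the observed ones, and a gene without reads in NESC could gain none in them. The simulated total is therefore no bar for the observed count. Across genes with at least 20 reads, the log2 fold changes correlated with r = 0.43, against 0.25 in the simulations. The 0.25 is fixed by setting 2 unchanged libraries against the same 3 NESC, so it is no bar for the observed r. The 3 NESC libraries cannot be divided into separate sets of at least 2, so the part of this overlap and correlation that comes from sharing the controls was not removed. The shared count was 0 with at least 20 reads, 0 by edgeR and 0 without any of NESC P5, P24 or P36.

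Passage 5 NESC were compared with passages 24 and 36, since the submitters scored their self-organisation as weaker. Most HOX genes of groups 6 to 9, which pattern the spinal cord, were read at passage 5 and almost nowhere else. The exception among those with at least 20 reads at passage 5 was HOXD8, with 59, 16 and 11 reads in NESC, 5 in RGPC and 11 in neurons. HOXB9 (ENSMMUG00000020869, chromosome 16, 32850925 to 32856103) had 1133 reads (116 FPKM) at passage 5 and was listed at 0 in the other 4 libraries. HOXA9 had 403 reads against 1 and 0, HOXB8 321 against 0 and 1, HOXB7 267 against 1 and 0, and HOXB6 113 against 0 and 0. HOXC8 (9.51 FPKM) was listed at 0 in both later passages. Of groups 1 to 5, HOXA5 had 37 reads at passage 5 and HOXB5 had 12, and neither was read later in NESC, while others stayed on, with HOXB4 at 21.1, 43.3 and 21.8 FPKM, HOXD4 at 52.0, 52.9 and 32.2 FPKM and HOXA2 at 16.2, 21.6 and 13.1 FPKM. The hindbrain and HOX list was higher at passage 5 (camera, adjusted p = 0.000200, and adjusted p = 0.755 with an estimated correlation). Of 14 members, 10 were higher, 0 passed the limma test, and 6 were up and 1 down adjusted over the list alone. HOXB5, HOXB6, HOXB8, HOXB9 and HOXC8 were under 1 FPKM in every other library and were tested only because passage 5 was higher. The filter thus favours a rise, and neither these counts nor the list p-value is free of it. By edgeR, 4 members rose, HOXB9 and HOXB8 (both adjusted p = 0.0159) and HOXB6 and HOXC8 (both adjusted p = 0.0494), and EGR2 fell (adjusted p = 0.0337).

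**Figure D3:**
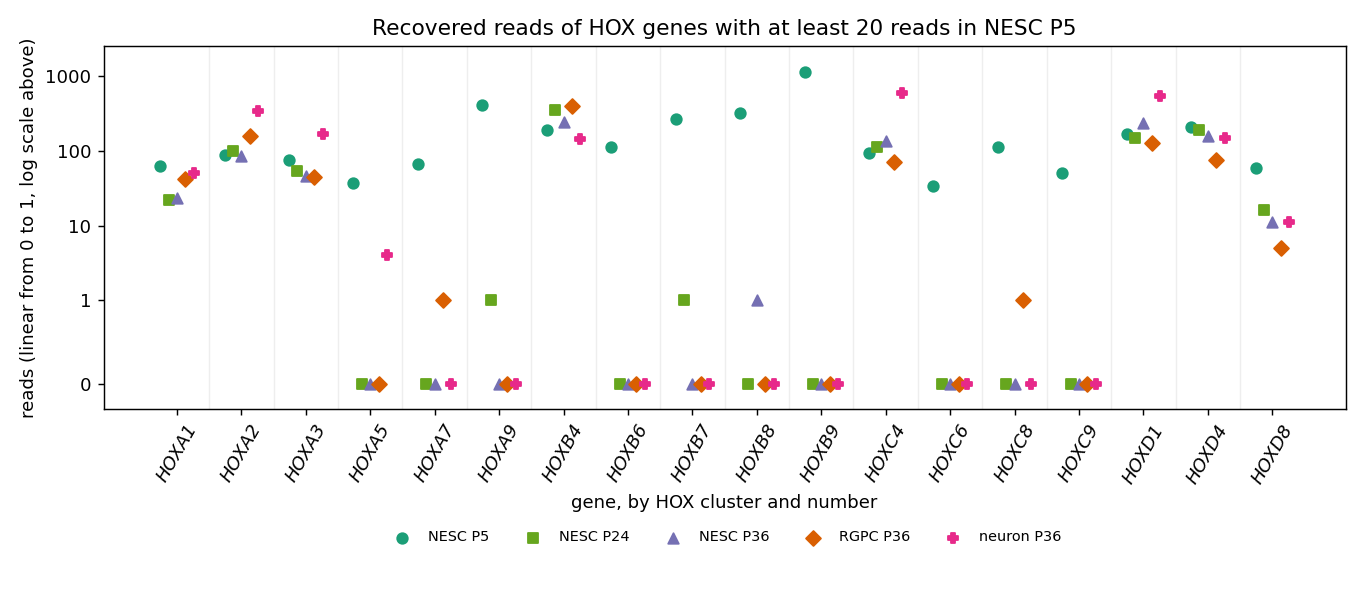
Recovered reads (y axis, linear from 0 to 1 and log above) of the 18 HOX genes with at least 20 reads in NESC P5, with 1 point per library and no error bars. HOXB9 had 1133 reads at P5 and 0 elsewhere, whereas HOXB4 was read in all 5 libraries.

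Targets of FGF and ERK were lower at passage 5. EGR1 was at 35.2 against 215 and 253 FPKM (−2.69 ± 0.18, edgeR adjusted p = 0.0291) and DUSP6 at 29.6 against 119 and 97.1 FPKM (−1.83 ± 0.21), and 13 of 14 list members were lower (camera, adjusted p = 2.36e-05, and adjusted p = 0.755 with an estimated correlation). Hedgehog pathway members were lower in 8 of 8 cases (adjusted p = 0.00838, and adjusted p = 0.755 with an estimated correlation), with 1 adjusted over the list alone. BOC, a Hedgehog co-receptor, was at 27.0 against 166 and 142 FPKM (−2.46 ± 0.16, edgeR adjusted p = 0.0369). Glycolysis was higher at passage 5 (19 of 20 members, adjusted p = 9.86e-05, and adjusted p = 0.755 with an estimated correlation), with 3 adjusted over the list alone. SLC2A3, a glucose importer, was at 358 against 59.9 and 61.6 FPKM (2.54 ± 0.09, edgeR adjusted p = 0.0159), SLC16A3, a lactate exporter, at 33.7 against 0.771 and 2.54 FPKM (3.79 ± 0.63) and BNIP3 at 529 against 43.8 and 116 FPKM (2.87 ± 0.86).

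Synaptic and proneural transcripts were also higher at passage 5. The synaptic list (19 of 21 members higher, adjusted p = 0.000689) and the proneural list (10 of 12, adjusted p = 0.0244, and adjusted p = 0.0639 with a pseudocount of 0.1) were up, and both gave adjusted p = 0.755 with an estimated correlation. The neuronal list did not pass (13 of 19 members higher, adjusted p = 0.137), and NEFL, a neurofilament, was lower at 101 against 301 and 253 FPKM, as was MAP2 at 22.7 against 28.0 and 53.5 FPKM. SYT4 was at 3.83 against 0.0416 and 0.119 FPKM (2.16 ± 0.18, edgeR adjusted p = 0.0159), and the proneural factors NHLH2 at 39.2 against 3.11 and 1.39 FPKM (3.68 ± 0.51, edgeR adjusted p = 0.0480) and NEUROD4 at 18.2 against 0.647 and 0 FPKM. Neuroepithelial and unfolded protein response lists were lower (10 of 14 and 11 of 15 members), and the small choroid plexus and retina list was higher (3 of 4 members). Each of these 3 lists gave adjusted p = 0.0487, adjusted p = 0.755 with an estimated correlation, and no call after quantile normalization (adjusted p = 0.275, 0.0862 and 0.221). PMEL, a pigment cell protein, was at 46.6 against 12.4 and 8.36 FPKM. CHAC1, a stress-induced gene, was at 71.3 FPKM in P36 alone, against 2.14 and 2.51 at passages 5 and 24.

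Some mesenchymal genes were higher at passage 5, among them the matrix genes LUM, at 20.3 against 0.942 and 0.298 FPKM (3.74 ± 0.37, edgeR adjusted p = 0.0418), COL3A1, at 33.7 against 4.06 and 0.0844 FPKM, and COL6A3, at 22.0 against 1.29 and 0.135 FPKM. The contractile gene TAGLN was lower, at 21.1 against 76.6 and 101 FPKM, and the fibroblast list gave adjusted p = 0.422, with 7 of 12 members higher (adjusted p = 0.0485 with at least 20 reads, 0.901 after quantile normalization and 0.755 with an estimated correlation). TFAP2B, a neural crest factor, was at 0.0980 against 19.7 and 29.0 FPKM (−4.50 ± 0.37, edgeR adjusted p = 0.0159), and MEOX1 at 0.280 against 78.1 and 40.6 FPKM (−5.49 ± 0.60, edgeR adjusted p = 0.0494). FST, an activin antagonist, was at 0.670 against 31.7 and 47.6 FPKM (−4.58 ± 0.40, edgeR adjusted p = 0.0301), the immediate early gene EGR3 at 0.294 against 16.9 and 51.4 FPKM, and THBS1, a matrix protein, at 6.30 against 168 and 134 FPKM (−4.37 ± 0.22, edgeR adjusted p = 0.0159). NES, SOX2, LEF1, AXIN2 and MKI67 did not pass with either tool. By fry the 9 list calls at passage 5 were lost (adjusted p = 0.404 to 0.793).

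By limma, 0 of 14571 genes passed at passage 5 (1459 at an unadjusted p under 0.05), and 0 of 12178 with at least 20 reads (1225 at an unadjusted p under 0.05, lowest adjusted p = 0.0748). edgeR called 32 up and 19 down (1532 at an unadjusted p under 0.05), and limma with a pseudocount of 0.1 called 121 up and 2 down. FHIT, FXYD7, PLEKHG1, FABP4, ZNF625 and C5ORF45, with at most 9 reads in any NESC library, had large fitted differences, and YBX1 had 12583 and 13772 reads at passages 5 and 36 but was listed at 0 in P24, RGPC and neurons.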

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

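The edgeR test and the minimum of 20 reads were chosen after seeing the data. No paired analysis was possible because RGPC and neurons had 1 library each, and only NESC P36 was of the passage they were made from. Where a NESC library was left out, the remaining pair gave 1 residual degree of freedom and the lone libraries were assumed to vary like it, and for passage 5 against later passages leaving out a library left no residual degree of freedom, so that was not run. How far depth limits genes with few reads was not measured. In simulations limma on all genes recovered 0% of changes of log2 3 for RGPC and for neurons, against 90% and 92% with at least 20 reads. The changed genes were all well read in NESC, so the 0% was no effect of few reads in them. It does not describe the neuron test either, which called 4013 genes on the deposited data. Simulated genes of like read level had the same spread, so the 90% and 92% do not give the power on the deposited data. Unless a cause follows from fewer genes or libraries, the cause was not tested. An estimated correlation left no list call in any comparison. Camera then rests on the few residual degrees of freedom, and some estimates were high, such as 0.70 for glycolysis in the model with 3 groups. Which of these removed the calls was not tested.

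For RGPC against NESC the 106 genes became 296 with no filter, 55 with a filter of 5 FPKM, 56 without a trend, 48 in robust form, 47 with only the compared groups, 0 with at least 20 reads and 0 by edgeR, and ranged from 0 to 0 when leaving out each NESC library. The other pseudocounts and scalings gave 72 to 150. The 4 list calls became 0 with an estimated correlation, 0 by fry, 9 after quantile normalization, 7 with at least 20 reads, and 2 to 7 when leaving out each library.

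For neurons against NESC the 4013 genes lay between 3376 and 4841 in all settings except leaving out each NESC library, which gave 0 to 927. The 9 list calls became 0 with an estimated correlation and otherwise numbered 7 to 9, though not the same lists, since by fry glycolysis, FGF and ERK targets and cholesterol synthesis were lost. For neurons against RGPC the 1101 genes became 1896 with no filter, 1836 with at least 20 reads and 0 to 530 when leaving out each library. The 5 list calls became 0 with an estimated correlation and 1 by fry (neurotransmitter). For passage 5 the 0 calls became 123 with a pseudocount of 0.1 and 51 by edgeR, and the 9 list calls became 0 with an estimated correlation and 0 by fry.

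Of genes at least 2-fold apart, the NESC pairs (passages 5 and 24, 5 and 36, 24 and 36) had 2644, 2780 and 2098 with a pseudocount of 0.1, 593, 781 and 477 with 5, and 991, 1115 and 559 with at least 20 reads. Passage 36 NESC and RGPC had 2980, 856 and 1267 under the same settings, and passage 36 NESC and neurons had 4064 with a pseudocount of 5. The 21 shared genes became 49 with a pseudocount of 0.1, 13 with 5, 90 with no filter, 12 with a filter of 5 FPKM, 13 without a trend, 9 in robust form, 0 with at least 20 reads, 0 by edgeR, and 0 to 0 when leaving out each NESC library.

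Direction turned for values near 0 in RGPC against NESC: SOX2 (0.041 after quantile normalization, and −0.14 to 0.061 when leaving out each NESC library) and MKI67 (−0.055 by edgeR, and −0.15 to 0.30). FABP7, at 0.86 as reported, also turned and ranged from −0.019 to 1.46 when leaving out each NESC library. The cell cycle list turned as well, with adjusted p = 0.988 by fry, 0.519 after quantile normalization, and 0.129 to 0.797 when leaving out each library (0.443 without P36, where it turned). In neurons FABP7 turned by edgeR (−0.36) and ranged from −0.79 to 0.69 when leaving out each library. Over the single genes of the text and all alternatives, neurons against NESC kept direction and side of the threshold 879 times, lost the call 134 times, gained it 51 times and turned 2 times. Neurons against RGPC kept 595, lost 92 and gained 40. RGPC against NESC kept 950, lost 30, gained 10 and turned 6, and passage 5 kept 661 and gained 19. Genes past the threshold in neither setting count as kept. At passage 5 no gene had a call to lose, and in RGPC no gene with at least 20 reads in a library had one, so these counts do not show stable calls.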

Other observations

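The tests on few reads, on HOX genes, on fibroblast markers, on a share of neurons and on scaling were chosen after the results they measure were seen, and earlier forms of those on HOX genes, on a share of neurons and on scaling were replaced after their values were known. Quantile normalization itself was fixed before the data were examined.

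Some position markers were looked at one by one. GBX2, a factor of the anterior hindbrain, was at 15.3, 46.9 and 44.5 FPKM in NESC at passages 5, 24 and 36, 26.5 in RGPC and 13.1 in neurons, and IRX3, of the caudal neural plate, at 66.1, 80.5 and 74.4 FPKM, 113 and 53.3 in the same order. Only 4 of 15 forebrain list members were in the table, so forebrain identity was barely measured, and LHX5 among them was at 2.74, 0.169 and 0.874 FPKM in NESC, 6.56 in RGPC and 48.4 in neurons. PAX3 was at 1.37, 35.6 and 50.4 FPKM in NESC, PAX7 at 1.42, 16.6 and 8.02 FPKM and EN2 at 1.23, 9.26 and 7.87 FPKM. NKX6-1 was at 11.6 FPKM at passage 5, listed at 0 at passages 24 and 36 and at 26.0 in neurons. At passage 5 against later passages, the dorsal list (2 of 9 members higher, adjusted p = 0.422), the midbrain list (3 of 8, adjusted p = 0.473) and the ventral list (2 of 4, adjusted p = 0.446) did not pass. PAX2, of spinal and hindbrain interneurons, was at 47.9 FPKM in neurons and at most 0.372 in NESC.

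The Notch ligand DLL1 was at 25.6, 18.4 and 34.9 FPKM in NESC, 62.6 in RGPC and 48.4 in neurons, and the receptor NOTCH3 at 17.7, 21.8 and 22.1 FPKM, 44.0 and 25.9. CDKN1A, a p53 target that halts the cell cycle, was at 151, 203 and 194 FPKM in NESC, 50.7 in RGPC and 32.1 in neurons. SALL4, a factor of early embryonic cells, was at 34.7, 55.8 and 43.2 FPKM in NESC, 76.8 in RGPC and 4.72 in neurons.

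FPKM of genes with few reads was weighed as the source of the 106 genes past the threshold in RGPC against NESC. Of these calls 100% had fewer than 20 reads in every library, against 16.4% of all genes tested, but this share describes the calls and does not test their source. In 20 simulations of an unchanged RGPC library, a mean of 12.2 genes passed (range 6 to 20), all with fewer than 20 reads. Those simulations could give no reads to a gene without reads in NESC, and named calls such as FLJ12892 and HCRT are of that kind. They could not produce such noise, so their count is no bar for the 106. Noise in genes with few reads cannot be told apart from a difference between RGPC and NESC in these genes. The larger differences in well-read genes are outside this set and did not pass the test (LEF1, adjusted p = 0.143), and a biological difference between RGPC and NESC stays open for them.

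Most HOX genes of groups 6 to 9 were read at passage 5 and almost nowhere else, except HOXD8 with 59, 16, 11, 5 and 11 reads in NESC, RGPC and neurons. Zeros from failed estimates, of the kind seen for YBX1, are argued against. Of the 18 HOX genes with at least 20 reads at passage 5, 50% dropped to 5% or less in every other library, against 0.0814% of 11054 other genes, and 5 of the 9 still had a read elsewhere. Mesenchymal cells in the passage 5 culture may contribute and cannot be told apart from a change in the NESC. Of 11 fibroblast markers with reads, 18.2% were below both later NESC libraries and 6 were above both, with COL3A1 at 910 reads at passage 5 and TAGLN at 101, against 328 and 597 later. The fibroblast list gave adjusted p = 0.422 at passage 5, and from 0.0485 with at least 20 reads to 0.901 after quantile normalization over its alternatives. A loss of posterior cells or identity with passage also stays open and was not tested.

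Neuronal transcripts were mostly higher in RGPC than in NESC (14 of 19 list members), though the list did not pass on the deposited values. A single share of neurons like those of day 13 in the RGPC culture is argued against. At the median share of 6.34% over 24 neuron-high genes, 20.8% had under 1/3 of the reads that share brings, among them MYT1L with 1 read against 68.8 and SYT4 with 82 against 351. Scaling as the whole source is argued against, since the mean log2 fold change of the list was 0.71 as deposited and 0.64 after quantile normalization. In both, 14 members were higher. The SE over the 19 members (0.20 after quantile normalization) describes genes of the lone RGPC library and measures no spread between cultures. The adjusted p of the list was 0.0990 as deposited and 0.0236 after quantile normalization, and over its other alternatives it ran from 0.00755 with at least 20 reads and 0.0497 without NESC P5 to 0.510 by fry and 0.785 with an estimated correlation, so whether the list differed at all stays open. Younger neurons arising in the RGPC culture may account for the pattern, but no test here could show it.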
